A study of Drosophila melanogaster with 2 samples.

How the data were processed

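The data were peak lists from 2 biological replicates of chromatin immunoprecipitation with an antibody against GFP from whole Drosophila embryos carrying a CG16779-eGFP fusion. Per the labels, the embryos were 8 to 24 hours old, chromatin was sonicated to fragments of 200 to 800 bp, and the assembly was dm6. The aligner, the peak caller, their versions and the treatment of the control library named in the labels were not given in the sources used here. That control was not analysed here. A hyphenated age in one label field had been turned into a spreadsheet date number, and the age was taken from the source name instead.

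Peaks were used as deposited by the authors. Each replicate had a ranked list (114279 peaks for replicate 1 and 119858 for replicate 2) and a list thresholded on the irreproducible discovery rate (IDR), which scores how reproducibly a peak is ranked in a pair of peak sets. Per the file headers and the descriptions deposited with them, 2 ranked and 2 thresholded lists were made from both replicates. The conservative list was a thresholded list from replicate 1 against replicate 2 (136703 ranked peaks), and the other came from pooled reads (137664 ranked peaks). The deposited signal value of a peak is the peak caller's own, on a scale and with a background treatment that were not given in the sources used here, so it was used only to describe, rank, correlate and compare peaks within a list, and differences and ratios of signal depend on that scale. The deposited −log10 of the IDR was used as a filter: peaks of every thresholded list had an IDR of at most 0.01. In the ranked list made from both replicates, 2 unnamed columns gave the signal of each peak in each replicate. Their replicate was settled by exact matches to the own lists of the replicates (106479 and 107258 of 136703 peaks), with 0 matches to the other replicate. Read depth is unknown, and intervals on shares of peaks cover counting error only.

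Gene models were taken from Ensembl release 115 and sequence from release 6 of the reference genome, whose chromosome lengths matched dm6. Peaks on arms 2L, 2R, 3L, 3R, 4, X and Y were analysed. Each summit was assigned to 1 class, in the order promoter (within 500 bp of any of 24111 TSSs), 5' UTR, coding exon, 3' UTR, noncoding exon, intron and intergenic. Shares were compared with 1000 circular shifts within each arm in a two-sided permutation test. Arms were compared with their share of length by an exact two-sided binomial test. A protein-coding gene counted as bound when a conservative summit lay within 500 bp of any of its TSSs. The 25 gene lists were compared with all other protein-coding genes by a two-sided Fisher's exact test, as were genes in divergent pairs. In matching the lists to the annotation, 8 symbols had no match and were not analysed here. Promoter and other peaks were compared in median signal by a two-sided permutation test with 100000 resamples. Motifs were searched on both strands within 50 bp of each summit and in a window of the same size centred 300 bp upstream on the plus strand, and compared by an exact McNemar test. For 8-mers, the 10 with the smallest p on 2L and 2R were tested on 3L, 3R, 4 and X. All p-values within a family were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05.

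The genes and peaks named were chosen by a rule. It took CG16779 with any peak within 2 kb; the 25 protein-coding genes with the highest mean signal among promoter peaks that lay within 100 bp of a summit in the own list of each replicate, with other genes near the same peak; up to 4 bound members with the highest signal of each list past the threshold and of the Hox, neuronal, muscle, cell cycle and Polycomb and trithorax lists; and the 5 strongest peaks over 500 bp from any TSS. The groups, tests, gene lists, motifs, this rule and most alternatives were fixed before the data were examined. Sets of 629 peaks ranked by signal, the comparison with peaks above the IDR threshold, the region around CG16779, gene biotypes, the count of each peak for a single gene of a divergent pair, motifs at promoter peaks against the upstream control and the addition of peaks absent from the conservative list were chosen after seeing the data.

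Alternatives were the list from pooled reads, the own list of each replicate, the strongest 1258 peaks of the conservative list, TSS distances of 250 and 1000 bp, other overlap distances, other controls for motifs and other expected shares. The tests were checked on simulated data. With 40% of 2516 random summits placed at TSSs, the location comparison recovered 40.3% beyond the random share, and with random summits 0 classes and 0 arms passed. For the gene lists, 1 of 100 simulations of 13968 genes with no changed list gave any list past the threshold. The mitochondrial ribosomal protein list, with a large share of its members added as bound, passed in 100 of 100. Power for smaller effects or shorter lists was not simulated. With an 8-mer placed in 3% of 2516 random windows, that 8-mer ranked first, and with none placed 0 passed. With no list effect, the permutation within strata of TSS number passed in 2 of 20 simulations. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.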

Results

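Chromatin immunoprecipitation followed by sequencing was carried out on whole Drosophila melanogaster embryos aged 8 to 24 hours that carried a fusion of the protein encoded by CG16779 to the green fluorescent protein eGFP. The chromatin was sheared by sonication to fragments of 200 to 800 bp, and the fusion protein was recovered with an antibody against GFP. The labels gave 2 biological replicates of this single group. A control library was not analysed here, so the question addressed was where in the genome peaks lay, and no comparison between conditions was made. The number of reads behind each replicate is unknown, since the peak lists hold none. All positions are 1-based on dm6, and signal is the value that the authors' peak caller gave each peak. Unless stated otherwise, signal is the mean ± SD of the 2 replicates (n = 2).

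CG16779-eGFP gave 2517 peaks that passed an irreproducible discovery rate (IDR) of 0.01 between the replicates, called here the conservative list. Of these, 2516 lay on the chromosome arms and were analysed. The list of peaks made from the pooled reads held 2705. Replicate 1 alone gave 1197 peaks and replicate 2 alone gave 1246, a ratio of 1.04. The conservative list was 2.02 times as long as the larger of these. Of the 2517 peaks, 2314 had the largest width in the list, 290 bp, so widths say little about the extent of binding.

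Most peaks of one replicate were also called in the other. Of the 1196 summits of replicate 1 on the arms, 777 (65.0%, 95% exact interval 62.2 to 67.7) lay within 100 bp of a summit of replicate 2, against 0.180% after circular shifts of the positions (one-sided permutation p = 0.001, the smallest that 1000 shifts allow). In the conservative list, 777 peaks (30.9%) lay at a summit in the own list of each replicate, and 1151 (45.7%) lay in neither. The median signal was 73.3 for the former and 35.6 for the latter. Across the 2516 peaks, which are not independent replicates and were selected for agreement between these same replicates, the signals of the replicates had a Spearman rho of 0.59, and the log2 ratio of replicate 2 to replicate 1 had a median of 0.02 and an SD of 0.41. Over all 136703 ranked peaks, rho was 0.33 and the SD 1.06.

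**Figure D1:**
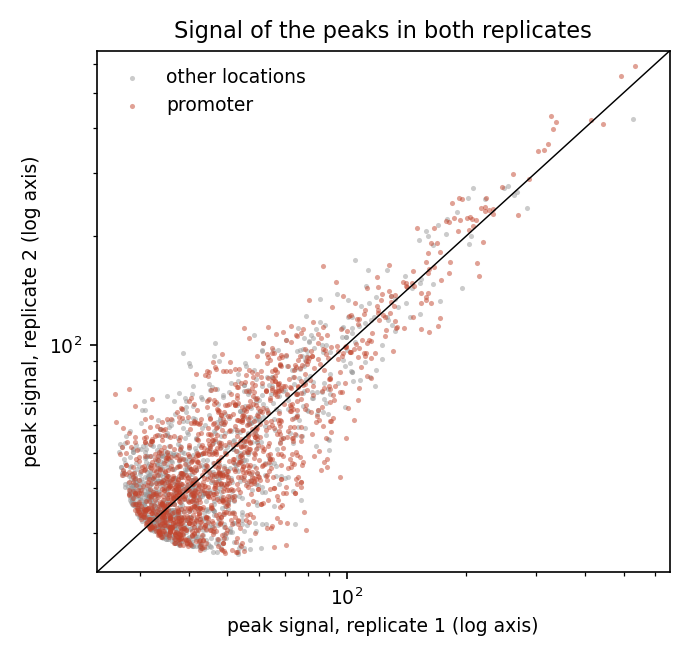
Peak signal in replicate 1 (x axis) against replicate 2 (y axis), both on log axes in the units of the authors' peak caller, for the 2516 peaks of the conservative list; red points are promoter peaks, grey points are peaks elsewhere, and the line marks equal signal. The log2 ratio of replicate 2 to replicate 1 had an SD of 0.288 in the 629 weakest peaks and 0.378 in the 629 strongest. It was larger in the sets of 629 peaks between them, at 0.452 and 0.497. The sets were cut on the mean of these same 2 signals, so the SDs do not rank how well peaks of different strength agree. Within the sets, from weakest to strongest, rho between replicates was -0.75, -0.83, -0.48 and 0.65.

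CG16779-eGFP peaks were concentrated at promoters. A summit lay within 500 bp of an annotated transcription start site (TSS) for 1391 of the 2516 peaks (55.3%, 95% exact interval 53.3 to 57.2), 4.06 times the 13.6 ± 0.825% (SD over 1000 shifts) obtained after circular shifts. The median distance from summit to TSS was 348 bp, against 3363 bp for shifted summits. Introns held 661 summits (26.3%, 39.1% after shifts), intergenic sequence 246 (9.78%, 27.7%), coding exons 163 (6.48%, 13.7%) and 3' UTRs 20 (0.795%, 4.33%), all below the shifted share. Each of these 5 differences had a permutation p of 0.002, the smallest that the shifts allow, and an adjusted permutation p of 0.0028. The shares in the remaining 5' UTR (18 summits, adjusted permutation p = 0.893) and in noncoding exons (17 summits, adjusted permutation p = 0.562) did not differ detectably from the shifted ones.

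**Figure D2:**
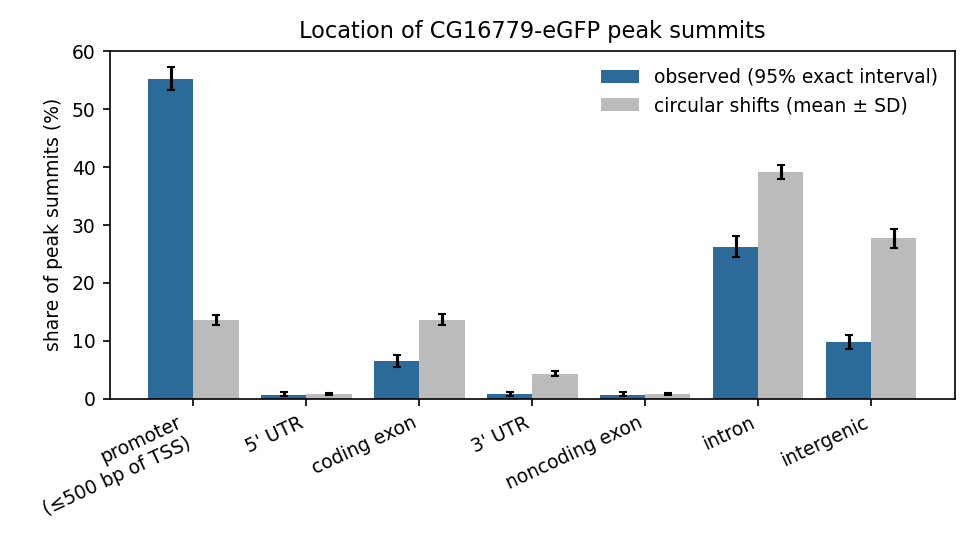
Share of peak summits (y axis, %) in each location class (x axis) for the 2516 peaks of the conservative list (blue, whiskers are 95% exact binomial intervals) and after 1000 circular shifts along each arm (grey, mean with SD). Promoters hold 55.3% of observed and 13.6% of shifted summits, and introns, intergenic sequence, coding exons and 3' UTRs hold less than their shifted shares.

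The location of peaks changed with their strength. Among the 629 weakest peaks, with signals of 31.4 to 36.0, 41.3% of summits were at promoters and 16.2% in coding exons. Among the 629 strongest, with signals of 59.7 to 564, the shares were 64.7% and 0.318%. Both differences passed Fisher's exact test (adjusted exact p = 2.3e-16 for promoters and 2.9e-29 for coding exons), as did intergenic sequence (12.1% and 7.47%, adjusted exact p = 0.0102), whereas introns did not (27.5% and 25.1%, adjusted exact p = 0.370). These sets were formed after the peaks had been examined. The median signal of promoter peaks was 46.2, against 40.1 for all other peaks (two-sided permutation p = 1.0e-05, the smallest that the resamples allow). That difference of 6.11 fell to 1.08 in the strongest 1258 peaks of the list (permutation p = 0.548) and to 2.62 in the own list of replicate 2 (permutation p = 0.0790).

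The strongest peak of all lay 28 bp upstream of a TSS of Ugalt, which encodes a UDP-galactose transporter (FBgn0024994, X, 2703753 to 2704011, signal 564 ± 42.4). The 31 bp around its summit, from 2703865 to 2703895, read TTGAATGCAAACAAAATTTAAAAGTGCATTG. It was followed by the promoter of CG14100 (FBgn0036889, 3L, 19590491 to 19590741, 524 ± 46.0), with the sequence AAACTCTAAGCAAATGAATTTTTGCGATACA from 19590595 to 19590625, and by a peak in an intron of CG11050 (2L, 6612602 to 6612842, 474 ± 73.4), 1019 bp from the nearest TSS. Next came the promoter that CenG1A, an Arf GTPase-activating protein, shares with the mitochondrial ribosomal protein gene mRpS23 (2L, 13835347 to 13835585, 426 ± 24.99). The sequence within 50 bp of these 4 summits had GC contents of 33.7%, 26.7%, 21.8% and 29.7%.

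Mitochondrial ribosomal protein genes stood at 4 of the 25 strongest promoter peaks of protein-coding genes that both replicates called on their own, although that group as a whole did not pass the test of gene lists. The 25 peaks had signals from 215 to 564, against a median of 42.9 for the list. They included CG7601 with its neighbour CIA30, a complex I assembly factor (3R, 29736728 to 29736965, 417 ± 4.68), PNPase, the mitochondrial polynucleotide phosphorylase (3R, 31404533 to 31404780, 379 ± 72.1), mRpL41 (2R, 15217638 to 15217855, 376 ± 54.6), Tcs5 with the ESCRT gene CHMP2B (3L, 5139382 to 5139612, 363 ± 45.7), eIF6, a factor of 60S ribosome maturation (2R, 23850291 to 23850501, 341 ± 27.4), and the arginine methyltransferase gene Art3 with mRpS10 (3R, 15229440 to 15229629, 331 ± 23.4). Further peaks stood at mRpL23 with CG9004 (3L, 2373520 to 2373692, 249 ± 29.8), at Elp5, a subunit of the Elongator complex, with CG1275 (3L, 2257413 to 2257601, 228 ± 15.2), and at Chro, the chromodomain protein Chromator, with Ssl1, a subunit of the transcription factor TFIIH (3L, 22878801 to 22878980, 224 ± 40.6). The others were at CG5611 with Mtl, CG1888, Fkbp14, CG8320 with Pex11ab, GstE13, tank, CG13390 with CG17294, CG18549, px, gish, CG3552 with CG3437, and moody, a receptor of the blood-brain barrier. The Polycomb group gene ph-p completed the 25. Of these summits, 20 lay upstream of the TSS, and 11 of the peaks lay near more than 1 gene. Signal in replicate 2 was the higher for 22 of them, and no pair of replicates differed by more than 1.34-fold.

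Away from promoters, 4 of the 5 strongest peaks were intronic. Besides CG11050 these were in CG3726 (X, 5918817 to 5919026, 267 ± 2.13), CG32772 (X, 4910263 to 4910473, 265 ± 14.2) and Tlk, the Tousled-like kinase gene (X, 3742121 to 3742307, 262 ± 2.34), 1263 to 2329 bp from the nearest TSS. An intergenic peak on 3R (16222392 to 16222591, 263 ± 32.4) lay 911 bp from the TSS of the noncoding gene lncRNA:CR45643.

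Ribosomal protein genes stood out among the 25 gene lists fixed before the data were examined. A summit lay within 500 bp of a TSS for 50 of the 86 cytoplasmic ribosomal protein genes (58.1%, 95% exact interval 47.0 to 68.7), against 11.0% of all other protein-coding genes (odds ratio 11.2, adjusted p = 2.3e-24 by Fisher's exact test). For these 50 genes the summit lay a median of 29 bp from the TSS, and 31 of the peaks were in the own list of each replicate. The strongest were at RpL7 (2L, 10200988 to 10201099, 142 ± 16.8), RpS27 (3R, 25247464 to 25247593, 141 ± 40.0), RpL14 (3L, 8600891 to 8601028, 137 ± 24.4) and RpL41 (2R, 24903969 to 24904072, 128 ± 7.86). All 4 peaks also lay within 500 bp of a TSS of another gene, in this order Ripalpha, Nup37, Nelf-E and NaCP60E. Such a high share was not particular to ribosomal protein genes. Of 31 abundant non-ribosomal genes, taken up below, 14 were bound (45.2%, 95% exact interval 27.3 to 64.0). Of other housekeeping groups, a summit lay near 13 of 73 mitochondrial ribosomal protein genes (17.8%, adjusted exact p = 0.388), 8 of 44 translation initiation factor genes (18.2%, adjusted exact p = 0.475), 7 of 86 oxidative phosphorylation genes (8.14%, adjusted exact p = 0.963) and 3 of 32 proteasome genes (9.38%, adjusted exact p = 1).

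Genes of chemosensory receptors and of the cuticle were almost free of peaks. None of 179 chemosensory receptor genes had one (0%, 95% exact upper limit 2.04, adjusted exact p = 7.8e-09). Among 122 cuticle protein genes only Cpr65Ec had one (3L, 7093373 to 7093662, 33.8 ± 7.94, 0.820%, adjusted exact p = 8.6e-05), and neither replicate called it alone. Over the genome, 1583 of 13968 protein-coding genes (11.3%) had a summit within 500 bp of a TSS.

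**Figure D3:**
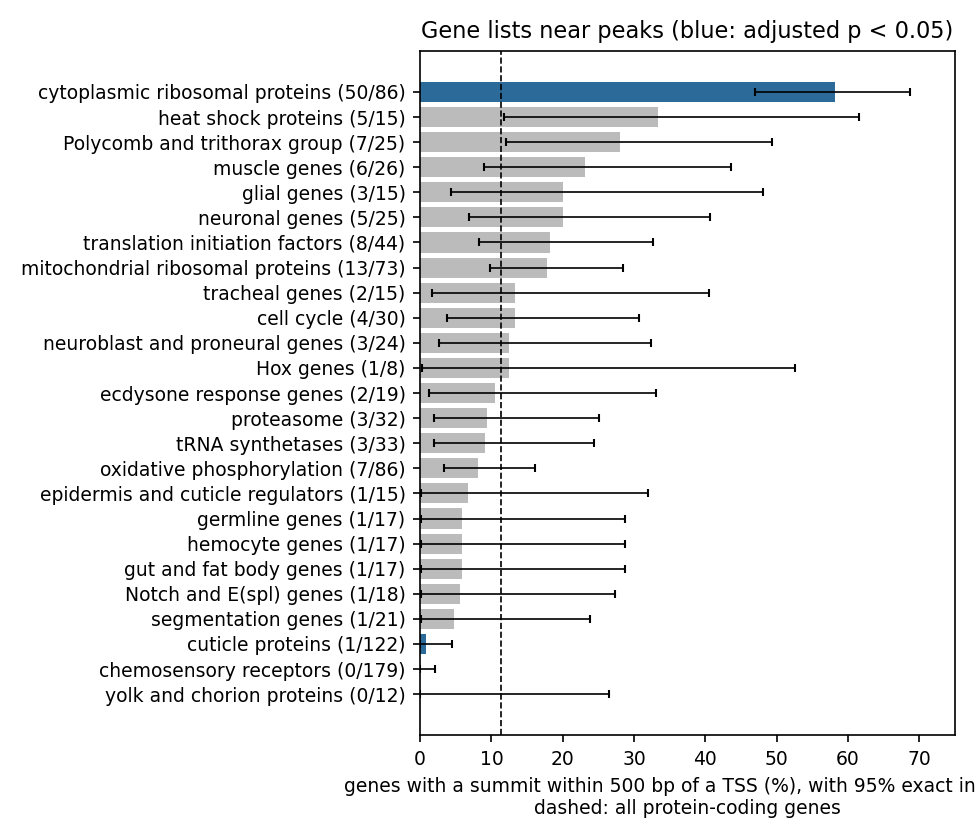
Share of genes with a peak summit within 500 bp of a TSS (x axis, %, whiskers are 95% exact binomial intervals) for each of the 25 gene lists (y axis, with bound and tested genes in brackets); blue bars passed an adjusted exact p of 0.05, and the dashed line is the 11.3% of all protein-coding genes. Cytoplasmic ribosomal protein genes reach 58.1%, while cuticle protein genes (0.820%) and chemosensory receptor genes (0%, no visible bar) also passed.

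Regulators of chromatin and of cell identity did not pass the test as groups in the conservative list. Among Polycomb and trithorax group genes 7 of 25 had a summit (28.0%, adjusted exact p = 0.105). The strongest were at ph-p, 500 bp upstream of a TSS (X, 2137239 to 2137454, 325 ± 29.0), brm, the SWI/SNF ATPase gene (3L, 15982933 to 15983076, 170 ± 14.03), Trl, which encodes the GAGA factor (3L, 14757049 to 14757338, 81.5 ± 15.99), and Su(z)2 (2R, 12996389 to 12996678, 54.5 ± 0.647). Heat shock protein genes had 5 of 15 (33.3%, adjusted exact p = 0.105). Both groups passed among the strongest 1258 peaks (adjusted exact p = 0.0326 and 0.0174). Heat shock genes also passed in the own lists of replicates 1 and 2 (adjusted exact p = 0.0122 and 0.0021), and Polycomb and trithorax genes in that of replicate 2 and in the pooled list (adjusted exact p = 0.0247 and 0.0326). In permutations within strata of TSS number neither group passed (1.93 times the expected number for Polycomb and trithorax and 3.21 for heat shock genes, adjusted permutation p = 0.465 and 0.137), nor did neuronal genes (1.02 times, adjusted permutation p = 1). Among 8 Hox genes only Antp had a peak (3R, 6932828 to 6933117, 37.5 ± 0.940, adjusted exact p = 1). Neuronal genes had 5 of 25 (adjusted exact p = 0.542, and 8 of 25 with the pooled list, adjusted exact p = 0.0326), led by elav (X, 523432 to 523542, 90.2 ± 21.6), brp (2R, 9503634 to 9503923, 69.6 ± 37.6), futsch (X, 1411700 to 1411989, 52.3 ± 20.1) and Rim (3R, 17916444 to 17916733, 39.1 ± 13.3). Muscle genes had 6 of 26 (23.1%, adjusted exact p = 0.393), with sns, a myoblast fusion gene (2R, 8798406 to 8798695, 63.2 ± 5.21), tin, a heart and mesoderm regulator (3R, 21378631 to 21378920, 63.01 ± 10.6), sls (3L, 2115745 to 2116034, 53.5 ± 1.66) and Mef2 (2R, 9929483 to 9929772, 36.1 ± 2.11). Cell cycle genes had 4 of 30 (13.3%, adjusted exact p = 0.963), which were Dp (2R, 13223251 to 13223540, 84.7 ± 7.94), dup (2R, 15380532 to 15380821, 54.3 ± 3.89), E2f2 (2L, 21156141 to 21156430, 48.1 ± 23.7) and CycE (2L, 15746674 to 15746963, 32.5 ± 4.55). None of the remaining 12 lists passed.

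Genes in divergent pairs were near a peak more often than other genes, in part because a peak between a pair counts for both of its genes. Of 4650 protein-coding genes whose 5' end lies within 1000 bp of that of a divergent gene, 791 had a summit near a TSS (17.01%, 95% exact interval 15.9 to 18.1), against 792 of the 9318 others (8.50%, 7.94 to 9.08; odds ratio 2.21, Fisher's exact p = 4.8e-48). That counting alone raises the first share. With each peak counted only for the gene with the nearest TSS, an alternative chosen after seeing the data, the shares were 10.5% (490 genes) and 7.88% (734 genes; odds ratio 1.38, Fisher's exact p = 2.6e-07). Counted in this way, the odds ratio was 1.35 to 1.53 in the own lists of the replicates, 1.36 in the pooled list and 1.37 among the strongest 1258 peaks.

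Peaks were spread over the large arms, with fewer than the share of length on X and on chromosomes 4 and Y. Arm 2R held 523 peaks (1.13 times its share of length, adjusted exact binomial p = 0.0038) and 2L held 478 (1.11 times, adjusted exact p = 0.0166). For 3L, with 550, and 3R, with 613, the difference did not pass (adjusted exact p = 0.0924 and 0.220). X held 345 peaks (0.801 times, adjusted exact p = 1.2e-05), chromosome 4 held 6 (0.243 times, adjusted exact p = 3.8e-05) and Y held 1 (0.0149 times, adjusted exact p = 3.7e-27). The deficit on X did not pass in the own lists of replicates 1 and 2 (0.889 times, adjusted exact p = 0.147, and 0.972 times, adjusted exact p = 0.951) or among the strongest 1258 peaks (0.961 times, adjusted exact p = 0.552). The excess on 2R did not pass in either own list (1.08 and 1.11 times, adjusted exact p = 0.251 and 0.118), nor that on 2L in the list of replicate 2 (1.13 times, adjusted exact p = 0.0815). Among the strongest 1258 peaks neither passed (2L 1.12 and 2R 1.09 times, adjusted exact p = 0.155 and 0.206). Against the share of peaks with an IDR above 0.01, a background chosen after seeing the data, chromosome 4 stood at 1.47 times, 2L at 1.07 and Y at 0.210, none of which passed (adjusted exact p = 0.366, 0.156 and 0.156). The deficit on X and the excess on 2R passed against that background (0.752 and 1.11 times, adjusted exact p = 1.0e-08 and 0.0233). With the share of protein-coding TSSs as the expectation, 2L, 2R and Y did not pass (1.01, 1.01 and 0.339 times, adjusted exact p = 0.786, 0.786 and 0.577), and 3L did (1.13 times, adjusted exact p = 0.0042). X and chromosome 4 also passed with that expectation (0.813 and 0.330 times, adjusted exact p = 1.2e-04 and 0.0046). Adding peaks absent from the conservative list, also chosen after seeing the data, made the excess on 3R pass (1.11 times, adjusted exact p = 0.0047).

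Of 17 sequence motifs, the core promoter element Motif 7 was enriched at summits, being present within 50 bp of 70 summits (2.78%) against 21 control windows centred 300 bp upstream (0.835%, 3.33-fold, adjusted exact McNemar p = 4.3e-06), and at 2.15-fold for the 1391 promoter peaks against windows at unbound promoters (58 and 27, adjusted exact p = 0.0064). The DNA replication-related element TATCGATA, the site of the factor DREF, was present at 40 summits and 17 controls (2.35-fold, adjusted exact p = 0.0181), and tracts of 8 A were present at 108 summits and 174 controls (0.621-fold, adjusted exact p = 5.3e-04). In that comparison with unbound promoters, these last 2 no longer passed (1.12-fold, adjusted exact p = 0.942, and 0.769-fold, adjusted exact p = 0.288). With the same promoter peaks against the upstream control, an alternative chosen after seeing the data, the former passed (2.53-fold, adjusted exact p = 0.0127) and the latter did not (0.667-fold, adjusted exact p = 0.0623). Neither passed in the own lists of replicates 1 and 2, at 1.67-fold and 1.90-fold for the former (adjusted exact p = 0.411 and 0.289) and 0.845-fold and 0.70-fold for the latter (adjusted exact p = 0.506 and 0.136). The former also did not pass in 51 bp windows (2.14-fold, adjusted exact p = 0.284), nor the latter among the strongest 1258 peaks (0.798-fold, adjusted exact p = 0.394). The GAGA factor site (380 summits, 378 controls, adjusted exact p = 1), the TATA box (308 and 330, adjusted exact p = 0.585) and the Initiator (263 and 247, adjusted exact p = 0.690) did not pass, nor did the CA repeat (72 and 89, adjusted exact p = 0.364). The GAGA site passed with opposite directions in alternatives, at 1.39-fold for promoter peaks against unbound promoters (adjusted exact p = 0.0064; 1.03-fold against the upstream control, adjusted exact p = 1), and at 0.751-fold in the own list of replicate 2 and 0.799-fold in the strongest 1258 peaks (adjusted exact p = 0.0207 and 0.0484). So did the TATA box, at 1.37-fold and 1.34-fold in these last 2 (adjusted exact p = 0.0183 and 0.0281), and at 0.823-fold in the pooled list and 0.828-fold against a downstream control (adjusted exact p = 0.0309 and 0.0433). So did the CA repeat, at 2.88-fold for promoter peaks against unbound promoters (adjusted exact p = 0.0030; 0.958-fold against the upstream control, adjusted exact p = 1), and at 0.511-fold and 0.50-fold in the own list of replicate 2 and the strongest 1258 peaks (adjusted exact p = 0.0364 and 0.0281). No direction is therefore given for these 3. Summit and control windows were not matched in GC content. Mean GC was 49.8% at summits and 40.2% in flanks for the 629 weakest peaks. For the 629 strongest peaks it was 37.4% and 42.9%. How far base composition accounts for the ratios of any motif was not tested. The Initiator passed for promoter peaks against the upstream control only (1.41-fold, adjusted exact p = 0.0127). The AP-1 site passed among the strongest 1258 peaks only (3.80-fold, adjusted exact p = 0.0281), and stood at 1.72-fold in the conservative list (adjusted exact p = 0.242). The homeodomain site passed for promoter peaks against unbound promoters only (0.676-fold, adjusted exact p = 0.0341), and stood at 0.850-fold in the conservative list (adjusted exact p = 0.364).

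A search over all 8-mers gave results that depended on the list and the control. Its control windows were not matched to summits in GC content either. The 10 highest-ranked 8-mers on 2L and 2R were tested on the 1514 peaks of 3L, 3R, 4 and X, where 5 passed, all enriched at summits, and 4 of the 5 contained CAGTG on one strand. This pentamer was noticed after the result, and its share was not tested. CAACACTG was present at 25 summits and 1 control (adjusted exact McNemar p = 8.0e-06), CACAGTGG at 29 and 8 (adjusted exact p = 0.0025), CAGTGGCG at 15 and 2 (adjusted exact p = 0.0064) and CAGCACTG, which fits the core of Motif 7, at 19 and 6 (adjusted exact p = 0.0293). The last was GATGGCGC, at 17 and 3 (adjusted exact p = 0.0064). Any of the 5 was present within 50 bp of 175 of all 2516 summits (6.96%), which include the summits on 2L and 2R used to choose them. Comparing the upstream with the downstream flank by the same procedure gave 0 of 10. Run on the own lists of replicates 1 and 2, the search passed 4 and 2 8-mers, of which 1 and 2 were enriched at summits and 1 and 2 contained CAGTG. With the pooled list 4 passed (2 enriched, 1 with CAGTG), with the strongest 1258 peaks 2 passed (1 enriched, 1 with CAGTG), and with a downstream control 3 passed (2 enriched, 1 with CAGTG).

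**Figure D4:**
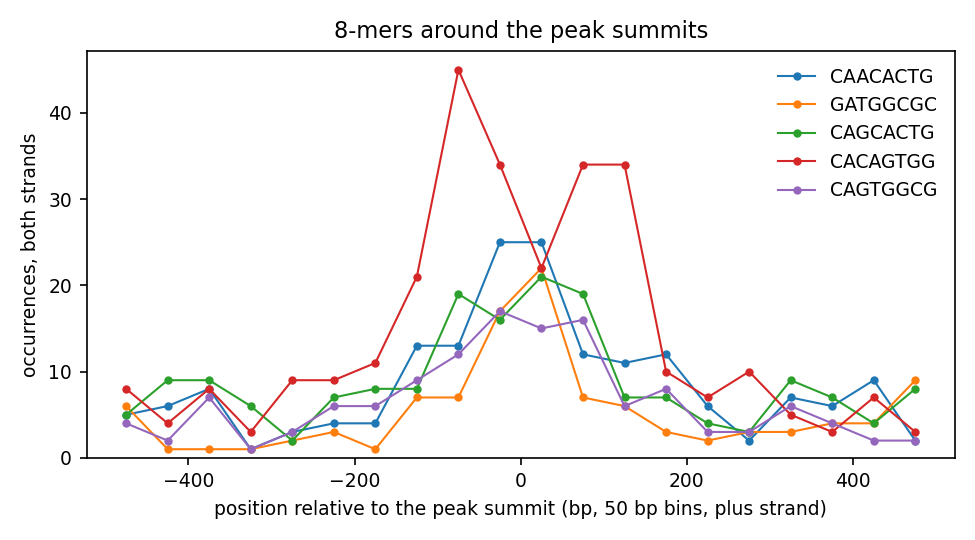
Occurrences of the 5 enriched 8-mers on both strands (y axis, count per 50 bp bin) by distance from the summit along the plus strand (x axis, bp) over the 2516 peaks; each line is 1 8-mer. All 5 are more frequent near the summit than 400 to 500 bp away, and CACAGTGG has 22 occurrences in the 50 bp after the summit against 45 in the bin from 100 to 50 bp before it.

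CG16779 itself lay in a region of raised peak signal. The gene (FBgn0037698, 3R, 9461084 to 9493677, minus strand) held 2 conservative peaks, both in introns, at 9491239 to 9491528 (50.6 ± 20.9) and 9482770 to 9483059 (49.0 ± 17.9). The last peak lay 366 bp beyond its 3' end (9460573 to 9460862, 50.1 ± 7.98), within 500 bp of a TSS of another gene. Each was called alone by a single replicate. For the region, the deposited signal of both replicates together was used, which is not comparable with the replicate means above. In the 100 kb centred on the gene, its median over the 130 peaks with an IDR above 0.01 was 32.8 (95% bootstrap interval 28.2 to 36.2). The median over 1155 other windows of that size was 22.9, and their highest value was 31.1. Each replicate by itself also showed raised signal, with medians of 18.7 in replicate 1 (12.6 over all such peaks) and 18.3 in replicate 2 (12.8).

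**Figure D5:**
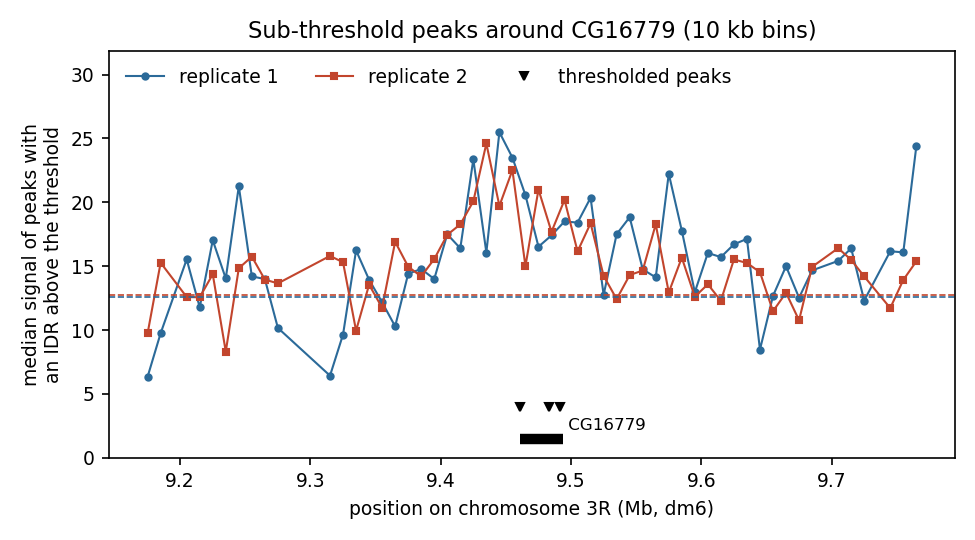
Median signal (y axis, units of the authors' peak caller) of peaks with an IDR above 0.01 in 10 kb bins along chromosome 3R (x axis, Mb, dm6) for replicate 1 (blue circles) and replicate 2 (red squares); dashed lines are the medians over all such peaks (12.6 and 12.8), the black bar is CG16779, triangles are conservative peaks, and bins with fewer than 5 peaks are not drawn. The medians around the gene are raised in both replicates.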

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

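The tests of the region around CG16779 and of the pooled housekeeping genes, and the addition of absent peaks, were chosen after the results were seen. The samples form 1 group, so no explanation was tested by comparing conditions. Explanations were weighed only by comparing genes, peaks and windows within that group.

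Peaks that met the IDR threshold of 0.01 but are absent from the conservative list were outside the comparisons above and numbered 108 of 2625. Of the 103 on the arms, 62 lay on 3R and 32 on 2L, and none on X; 45 had the next one within 10 kb on the same arm. The thresholded lists had a further input that the ranked lists did not, which was not described in the sources used here. Whether it was a list of regions to exclude, and removed these peaks, was not tested, so they may not be of the same kind as the others. In the list from pooled reads 113 such peaks were absent, 95 of them identical. They included strong peaks near cbt (2L, 480961 to 481215, signal 424 ± 0.109, n = 2), Lk6 (3R, 11760928 to 11761144, 341 ± 39.4) and larp (3R, 28326485 to 28326701, 267 ± 0.114), ranks 5, 11 and 17 of all peaks that met the threshold. Adding the 103 peaks left the promoter share at 4.05 times its shifted value and the number of gene lists with a higher share at 1. The arms did change: 3R went from 1.04 to 1.11 times its share of length (adjusted exact p = 0.220 and 0.0047), so 6 arms passed and not 5.

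Peak signal was raised around CG16779 in both replicates, including peaks with an IDR above the threshold. Window signals in this paragraph are those of both replicates together. A candidate explanation is extra DNA copies of the locus in the transgenic strain, which would raise signal at weak and strong peaks alike: the median signal of peaks above the IDR threshold in the 100 kb around the gene was above that of every other window of the 5 large arms (percentile 100), at 1.43 times the median window. The density of TSSs was argued against as the whole cause, although the number of TSSs and the median signal of windows were related (rho 0.47). A linear fit over the other windows predicted 23.3 for its 25 TSSs, and even the lower bootstrap limit, 28.2, exceeded the fit by more than 96.1% of the other windows did. The design of the transgene was not given in the sources used here, and binding of the protein across its own locus stays open. The comparison with other windows restates the pattern that prompted the candidate, so it cannot decide between extra copies and such binding.

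Stronger peaks were AT-richer. Mean GC content within 50 bp of the summit was 49.8 ± 9.87% (SD over 629 peaks) in the 629 weakest peaks and 37.4 ± 10.5% in the 629 strongest, while flanks had 40.2 ± 10.9% and 42.9 ± 10.2%. A GC bias of the libraries that lowers signal at GC-rich sites was argued against, because peaks above the IDR threshold showed the opposite relation (Spearman rho of GC and signal 0.20 across 132856 peaks, against -0.41 in the conservative list). Location was argued against as the whole cause, because rho was -0.37 within promoter peaks (bootstrap SD 0.025). The rho of 0.20 has the sign that a GC bias raising signal at GC-rich sites would give. The -0.41 of the conservative list has the other sign. Such a bias was not tested further and stays open. So do a bias of the peak caller and what sets the base composition of strong sites.

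Ribosomal protein promoters were bound. That housekeeping promoters are bound alike was argued against by gene lists already given above. Of their proteasome, oxidative phosphorylation and mitochondrial ribosomal protein genes, 23 of 191 were bound (12.04%, 95% exact interval 7.79 to 17.5). This pool was formed after the counts of its lists were known, so it is not separate evidence. Translation initiation factor genes, outside the pool, had 8 of 44 (18.2%, interval 8.19 to 32.7). The interval of ribosomal protein genes was 47.0 to 68.7. The number of TSSs per gene was argued against too, with 4.09 times as many ribosomal protein genes bound as in permutations within strata. That very highly transcribed genes are bound alike remained possible. Of 31 abundant non-ribosomal genes, listed before their peaks were looked up, 14 were bound (45.2%, interval 27.3 to 64.0), among them eEF1alpha1, eEF2, Act5C, Gapdh2 and Hsp83. Their share exceeded that of other genes (exact p = 2.2e-06) and did not differ detectably from the 58.1% of ribosomal protein genes (exact p = 0.293), so signal that follows transcription at any such gene, with or without the tagged protein, may account for part of the pattern. A control immunoprecipitation, not analysed here, would be needed to separate them.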

How the results depend on the processing

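Over the alternatives of 39 results, not counting single peaks, 217 of 298 values kept their direction and side of the threshold or stayed close, 24 no longer passed, 15 newly passed, 15 moved and 27 changed direction. The 27 were counted by direction only, whichever side of the threshold they fell on. Among them, values of the GAGA site, the TATA box and the CA repeat newly passed. Chromosome 4 no longer passed against peaks above the IDR threshold. The promoter share stayed 2.84 to 6.12 times its expected value in every alternative (3.44 times against peaks above the IDR threshold, chosen after seeing the data), and the odds ratio of divergent promoters stayed between 2.09 and 2.497 where a peak counts for both genes of a pair, but was 1.38 with each peak counted once (chosen after seeing the data). Replicate overlap ranged from 59.7% to 66.0%. Where values below differ, the cause was not tested.

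Among the strongest 1258 peaks, 2 arms passed, 3 lists had a higher bound share, 6 motifs and 2 8-mers passed, the promoter excess in signal was 1.08, the odds ratio of Hox genes was 0, and ratios were 0.965 for 3L, 0.799 for the GAGA site and 1.34 for the TATA box. With the list from pooled reads, 3 lists had a higher bound share, rho between replicates was 0.51, the 5' UTR ratio was 1.11 and the GAGA ratio 0.966. In 51 bp windows of the conservative list the GAGA ratio was 0.796. Leaving out a replicate in turn gave 2 to 3 arms, 2 to 3 lists with a higher share, 1 to 4 motifs, 2 to 4 8-mers, a promoter excess in signal of 2.62 to 4.34, 5' UTR ratios of 0.994 to 1.04, noncoding exon ratios of 0.775 to 1.13, Hox odds ratios of 0 to 2.07 and neuronal odds ratios of 0.587 to 2.76, with ratios of 0.970 to 0.987 for 3L, 0.996 to 1.04 for 3R, 0.751 to 0.881 for GAGA, 1.14 to 1.37 for TATA and 0.913 to 1.07 for the Initiator. With a TSS distance of 250 bp the 5' UTR ratio was 1.07, and with 1000 bp the Hox odds ratio was 0.864. In strata of TSS number, the ratio of bound to expected genes was 0.667 for Hox and 0.971 for cell cycle genes. Expecting peaks by TSSs, 3 arms passed. Of alternatives chosen after seeing the data, expecting peaks by the share of those above the IDR threshold gave 2 arms with 1.47 times for chromosome 4 and 0.986 for 3R, adding the absent peaks gave a 5' UTR ratio of 1.15, and a downstream control gave 3 8-mers. For promoter peaks against unbound promoters the CA repeat ratio was 2.88. Read depth is unknown, so what depth limits could not be stated, and each replicate's own list was less than 0.5 times as long as the conservative list.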

Other observations

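All comparisons of this part were chosen after seeing the data. Other gene classes differed in how often they carried peaks. A conservative summit lay within 500 bp of 6 of 290 tRNA genes (2.07%, 95% exact interval 0.763 to 4.45, against 9.56% of all other genes, adjusted exact p = 1.1e-06), 107 of 3289 noncoding RNA genes (3.25%, adjusted exact p = 1.1e-49) and 5 of 330 pseudogenes (1.52%, adjusted exact p = 1.1e-08). Small nuclear RNA genes (5 of 32, 15.6%, adjusted exact p = 0.221) and small nucleolar RNA genes (19 of 269, 7.06%, adjusted exact p = 0.221) did not differ detectably from the rest.

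Within the conservative list, none of the 629 weakest peaks was in the own list of both replicates, against 586 of the 629 strongest. In sets of 629 peaks of rising signal, coding exons held 16.2%, 8.43%, 0.954% and 0.318% of summits, and 24.6% of draws from peaks above the IDR threshold. The 8-mers that passed were present within 50 bp of 5.72% of the 629 weakest and 7.47% of the 629 strongest peaks, and of 7.76% of promoter and 5.96% of other peaks, so most strong peaks held none of them.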
